A study of Mus musculus with 6 samples.

How the data were processed

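Ribosome profiling, which sequences the short mRNA fragments covered by ribosomes, was compared between 3 libraries of resting and 3 libraries of activated mouse CD4+ T cells. Per the labels' protocols, the cells were purified by negative selection from spleen and lymph nodes of female C57BL/6J mice, and activation used beads carrying antibodies against CD3 and CD28. All 6 libraries are labelled 0 h and untreated, read here as before any treatment with an inhibitor of transcription or translation. The label does not cover inhibitors that may be used at harvest or lysis. How long the activated cells had been stimulated is not given in the sources used here. The labels call the libraries biological replicates and number them 2, 3 and 4 in both groups. They do not say whether each came from a separate animal, culture or pool of cells, so p-values measure the spread between these libraries.

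The authors deposited 1 table of raw counts for 22322 genes, with 36 count columns, 6 per library. Per the file headers, the columns count records in coding sequence (CDS) in 2 counting modes, in the 5' UTR, in the 3' UTR, in all exons and in introns alone. The deposited table held no fold changes or p-values, although its name speaks of statistics, so no comparison with the authors' own statistics was made. TopHat2 2.0.13, Bowtie 1.1.1.0, HTSeq (version not given) and genome build mm10 are named, per the submitters' processing notes. The annotation release, adapter trimming, fragment length limits, ribosomal RNA removal and strand setting are not given in the sources used here. Without the strand setting, records of overlapping genes on opposite strands cannot be assigned with certainty.

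The table also holds summary rows that name no gene. They were kept out of library sizes and tests. For the CDS columns, between 65.8% and 79.6% of all records of a library were not uniquely aligned, between 11.8% and 14.5% lay in no CDS, and between 0.0398% and 0.0985% were ambiguous. Genes with near-identical copies lose their records to the first of these classes, so their counts are uncertain. A record that aligns several times may be listed several times, so these totals count alignments and not molecules. In each library the first CDS column was at or below the CDS column in intersection-nonempty mode for every gene, and it was used as the main CDS count. The 5' UTR, 3' UTR and intersection-nonempty CDS counts summed to between 100.5% and 100.6% of exon counts per library. Which side of a start codon a record on the border was counted on is not given in the sources used here.

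The genes carry versioned Ensembl IDs and no names. The reference table of gene names given here, for assembly GRCm38.p6, listed no Ensembl IDs, so 0 of 22322 IDs matched a symbol, and the files do not pair them. The tests planned for 34 fixed gene lists (pathways, cell type markers and complexes) therefore could not be run, and neither could the share of footprints on those lists. The rule for named genes, fixed before the data were examined, took 4 parts. The first took the 10 highest and the 10 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups, leaving out unnamed genes and antigen receptor segments. The others took members of each list, a fixed set of genes by symbol, and the 5 most abundant genes of each group. Without symbols, only the highest 2 and the lowest 2 IDs of the first part are printed, with its exclusions by symbol not applied, and the most abundant genes are described without their IDs.

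Library sizes in the fit were the sums of CDS counts over the genes that passed the low-count filter, multiplied by TMM factors. Shares of counts used the sums over all genes. CDS counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr on the group, TMM factors, estimateDisp, glmQLFit, glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a gene comes from edgeR's quasi-likelihood test unless another tool is named. Standard errors (SE) of log2 fold changes were taken as the size of the change over the square root of its F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. Shares of counts per library were compared with exact two-sided permutation tests over the 20 assignments of the 6 libraries. Their smallest possible p is 0.1, so this design cannot reach 0.05. There were 23 such measures, adjusted together. Wilson intervals at 95% for the shares of single libraries cover counting error only.

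All analyses of the 5' UTR, the 3' UTR and introns were added after the data had been seen. Changes in 5' UTR counts relative to CDS counts of the same gene were tested in 1 edgeR model over both kinds of count, with a term per library, a term for the region and a term for the region in activated cells. Each region had its own TMM scaling in it. Genes needed at least 5 counts in the 5' UTR and at least 10 in the CDS in 3 libraries or more. No matched RNA counts were used here, so footprint counts are not divided by mRNA level and translational efficiency was not measured.

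Both fits were tested on simulated data, drawn from the library sizes of the real libraries and from gene means pooled over both groups. The spread was the same for all genes and libraries, and the counts of the CDS and the 5' UTR were drawn independently. Far fewer genes were changed than were called in the real libraries, and spread that differs between genes or libraries was not simulated. The false calls therefore do not give the rate in the real fits. For CDS counts, with 6650 genes run, 17.2% of genes changed 1.5-fold, 60.6% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 2 false calls. For the 5' UTR relative to the CDS, with 3433 genes run, 18% of genes changed 2-fold and 68% of those changed 4-fold were recovered, with 1 false call.

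CDS counts summed to between 437200 and 1074656 per library. Replicates were checked for duplicated libraries: chi-square over degrees of freedom of CDS counts lay between 1.80 and 2.05 for pairs of resting libraries and between 2.99 and 4.35 for pairs of activated libraries, so no 2 libraries were alike within sampling noise. Alternatives chosen before the data were examined were RLE, upper quartile and unscaled library sizes, other low-count filters, a block for the replicate number, DESeq2 1.42.0, limma voom (limma 3.58.1), other quasi-likelihood fits, a stricter threshold, a test against a 2-fold null and leaving out each library. Other counting columns, libraries thinned to the smallest total and scaling without the 50 most abundant genes were added later, as were abundance classes by the mean of log2 CPM.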

Results

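Ribosome footprints were counted per gene in 3 libraries of resting and 3 libraries of activated CD4+ T cells, helper T lymphocytes taken from mouse spleen and lymph nodes. The study as a whole followed how mRNA is lost with and without translation. These libraries hold its starting state, labelled untreated, in cells that had or had not been activated through CD3 and CD28. The comparison available here is therefore where ribosomes lay in activated cells and where they lay in resting cells. CDS counts summed to 437200, 565820 and 594508 in resting replicates 2, 3 and 4, and to 511483, 910575 and 1074656 in activated replicates 2, 3 and 4. Between 10322 and 11004 genes had a CDS count in a library. Of 22322 genes in the table, 12873 had a CDS count in any library and 6775 passed the low-count filter. These 6775 genes held 97.5% of all CDS counts.

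CDS footprints differed between activated and resting cells for 3097 of the 6775 genes tested (45.7%). Footprints rose for 1633 genes and fell for 1464. By at least 2-fold, 999 genes rose and 734 fell. Large changes were mostly rises: 286 genes rose and 41 fell by at least 4-fold, and 100 rose and 0 fell by at least 8-fold. More genes rose than fell at 4-fold and at 8-fold under each of the scalings run (188 and 145 at 4-fold, 69 and 1 at 8-fold, with library totals alone). The median log2 change was 1.18 among genes that rose and -1.0 among genes that fell. The values of the groups did not overlap in 3716 of the 6775 genes (54.8%, against 10% by chance for 3 libraries against 3). The spread between libraries of a group was small beside these changes, with a biological coefficient of variation of 0.146.

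The balance of rises and falls depended on the scaling between libraries. TMM factors were 1.12 to 1.13 in resting libraries and 0.880 to 0.894 in activated libraries, and the median log2 change over all genes tested was -0.04. With upper quartile factors that median was -0.18, and 1399 genes were higher and 1897 lower (844 and 936 by at least 2-fold). With library totals alone it was -0.38, and 1102 genes were higher and 2572 lower (682 and 1390 by at least 2-fold). RLE factors gave 1643 higher and 1452 lower, close to TMM. DESeq2 gave 1391 higher and 827 lower (1031 and 534 by at least 2-fold), but it also differs in its test and filter, so its balance does not come from scaling alone. Directions of genes are therefore relative to the TMM scaling, and no spike-in was used here that would fix an absolute level.

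Of the 2 genes with the highest fitted log2 changes, ENSMUSG00000024912.5 had 0 CDS counts in each resting library and 23, 20 and 21 counts in the activated libraries. Against a floor of 3 counts over the resting group, and with the activated counts taken as measured, it was at least 17.1-fold higher in activated cells, at 33.3 ± 16.5 CPM (SD, n = 3; edgeR adjusted p = 3.08e-05). ENSMUSG00000038264.7 rose from 6.10 ± 2.73 to 576 ± 242 CPM (SD, n = 3), a log2 change of 6.48 (SE 0.38, edgeR adjusted p = 2.47e-09). Its resting level rests on 2, 3 and 6 counts, against 208, 320 and 801 in activated cells. The order of these 2 genes is not settled, since the fitted change of the first depends on a group at 0, and limma voom gave log2 changes of 5.05 for ENSMUSG00000024912.5 and 6.34 for ENSMUSG00000038264.7. Of the genes that fell furthest, ENSMUSG00000029385.13 went from 84.4 ± 1.5 to 13.4 ± 4.17 CPM (SD, n = 3), a log2 change of -2.73 (SE 0.28, edgeR adjusted p = 7.77e-07). ENSMUSG00000045092.8 went from 858 ± 40.5 to 135 ± 41.2 CPM (SD, n = 3), a log2 change of -2.65 (SE 0.19, edgeR adjusted p = 2.03e-08). In libraries thinned to the smallest total and in exon counts, the log2 change was -1.97 and -2.10 for ENSMUSG00000029385.13. For ENSMUSG00000045092.8 it was -2.60 and -2.69, so the order of these 2 genes is not settled either. All 4 genes kept their direction under each of the scalings run. Among the 2974 genes that met the rule's conditions, the tenth gene from the top had a log2 change of 5.26 and the tenth from the bottom -2.25.

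**Figure D1:**
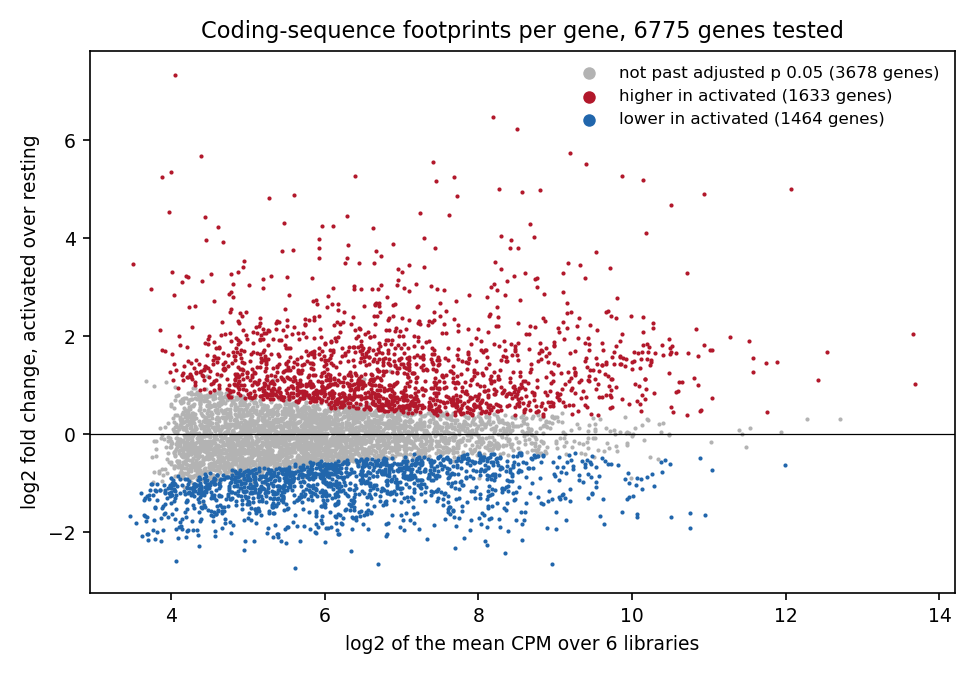
Log2 fold change of CDS footprints, activated over resting (vertical axis), against log2 of the mean CPM over the 6 libraries (horizontal axis), with each point a gene tested. Genes that rose (1633, red) reach a log2 change of 7.32, a fitted value for a gene at 0 in the resting libraries, and genes that fell (1464, blue) reach -2.73.

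Abundant genes passed the threshold more often than rare genes. Genes were split into 5 classes of 1355 by their mean over all 6 libraries. In the least abundant class 31.3% of genes changed, with 150 higher and 274 lower (104 and 473 with library totals alone). In the most abundant class 66.6% changed, with 566 higher and 336 lower, a balance that turned to 422 higher and 526 lower with library totals alone. The share that was higher went from 11.1% in the least abundant class to 41.8% in the most abundant, while the share that was lower went from 20.2% to 24.8%. Falls of at least 2-fold went the other way, with 218 in the least abundant class and 130 in the most abundant. Precision grows with the count, so the share of genes past the threshold also follows depth. A mean over both groups also places a gene that rose higher than a gene that fell. With classes by the mean of log2 CPM, which weighs rises and falls alike, 188 genes were higher and 284 lower in the least abundant class, and 537 and 338 in the most abundant.

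Footprints were concentrated on fewer genes in activated cells. The 10 most abundant genes of a library held 4.98 ± 0.15% of CDS counts in resting and 7.95 ± 0.28% in activated cells (SD, n = 3). The 100 most abundant held 18.7 ± 0.16% and 24.7 ± 0.27%. The number of genes that together held 50% of CDS counts was 747 ± 8.62 in resting and 506 ± 5.51 in activated cells. At the smallest total of 437200 counts, 10382 ± 50.7 genes would be detected in resting and 10024 ± 90.1 in activated libraries. For each of these 4 measures the groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 can give (0.256 after adjustment over 23 measures).

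The most abundant gene was a different gene in each group, and both of these genes rose. The most abundant gene of activated cells held 0.545 ± 0.055% of CDS counts in resting and 1.80 ± 0.09% in activated cells (log2 change 2.05, SE 0.17, edgeR adjusted p = 1.06e-07). The most abundant gene of resting cells went from 0.952 ± 0.049% to 1.54 ± 0.18% (log2 change 1.02, SE 0.17, edgeR adjusted p = 0.00012). The groups shared 5 of their 10 and 41 of their 100 most abundant genes. The genes that rose by at least 2-fold held 14.5 ± 0.10% of CDS counts in resting and 38.6 ± 1.63% in activated cells, and the genes that fell by at least 2-fold held 13.7 ± 0.54% and 4.09 ± 0.34%. Those genes were chosen on the same libraries, so these shares describe the size of the change and do not test it.

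**Figure D2:**
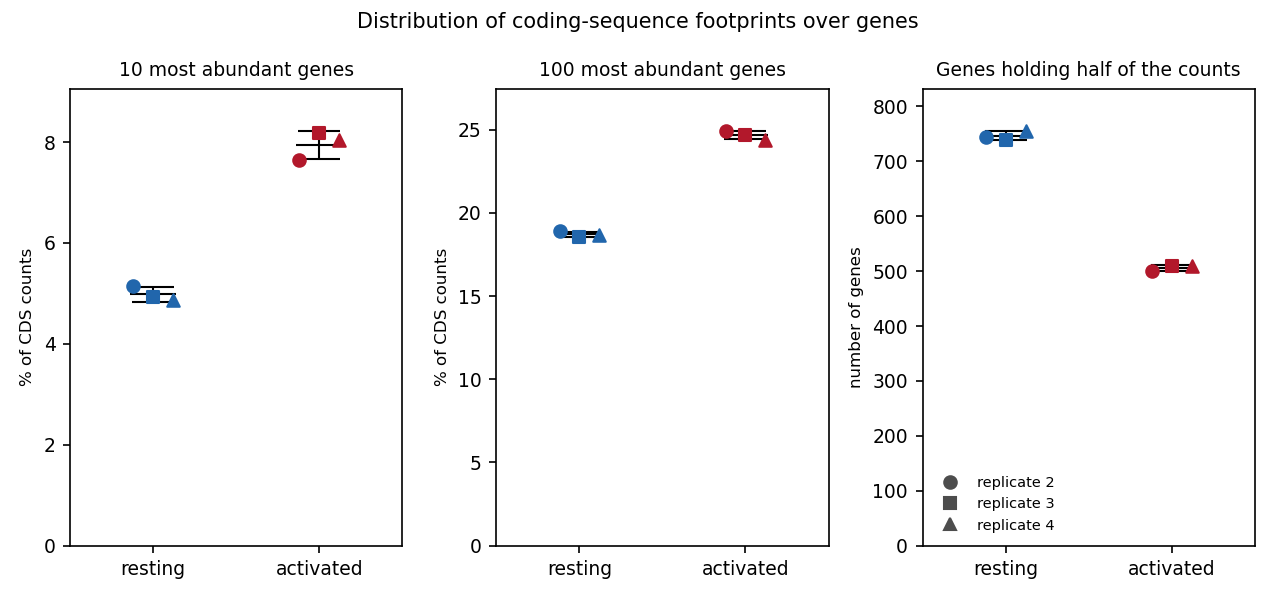
Share of CDS counts (percent) on the 10 and the 100 most abundant genes of each library, and the number of genes holding 50% of CDS counts, in resting (blue) and activated (red) libraries. Points are libraries, with their shape giving the replicate number, and bars are the mean ± SD (n = 3); the 10 most abundant genes held 4.98% on average in resting and 7.95% in activated cells.

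Of the counts on exons and introns, most lay in coding sequence. Uniquely aligned records also include those outside exons and introns. Of them, the CDS held 42.0%, 38.6% and 46.2% in resting replicates 2, 3 and 4. In activated replicates 2, 3 and 4 it held 39.5%, 55.9% and 59.0%. CDS counts were 69.0 ± 3.86% of exon and intron counts in resting and 73.7 ± 1.78% in activated cells (SD, n = 3; exact permutation p = 0.2). The 5' UTR held 10.3%, 10.1% and 9.72% in resting replicates 2, 3 and 4, and 14.4%, 11.4% and 10.6% in activated replicates 2, 3 and 4. All activated libraries were above all resting libraries (exact permutation p = 0.1, adjusted 0.256), and the 95% Wilson interval of each share had a half-width of at most 0.0814 percentage points. Without activated replicate 2 the difference between the means fell from 2.08 to 0.951 percentage points. Over exon counts alone the groups overlapped, at 11.02%, 12.03% and 10.97% in resting and 15.16%, 11.98% and 11.47% in activated replicates 2, 3 and 4, a difference of 1.53 percentage points (exact permutation p = 0.3). The base of exon and intron counts includes introns, which held most in resting replicates 3 and 4 (16.3% and 11.4%). That lowers the CDS and 5' UTR shares there, so the separation of the groups in the 5' UTR share depends on the base. Per 100 CDS counts, the 5' UTR had 14.6 ± 0.85 counts in resting and 16.5 ± 3.09 in activated cells, and the groups overlapped (exact permutation p = 0.5).

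Gene by gene, 5' UTR counts moved largely with those of the CDS. Of 2200 genes tested on 5' UTR counts alone, 488 rose and 436 fell. Upper quartile factors gave 416 higher and 515 lower, library totals alone gave 368 higher and 592 lower, and DESeq2 gave 363 higher and 223 lower. Over the 2073 genes tested in both regions, the log2 changes had a Pearson correlation of 0.89 across genes, which are not independent replicates, and 83.1% had the same sign. The 735 genes that changed in both regions all changed in the same direction. Both counts come from the same 6 libraries.

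Relative to the CDS, 5' UTR counts changed in 21 of 3433 genes tested (394 genes at an unadjusted edgeR p under 0.05). Of the 21, 8 were higher and 13 lower in activated cells. Each region was scaled on its own, so higher and lower are relative to the shift of the typical gene and not to the raw ratio. Log2 changes of a ratio use that scaling here unless 1 scaling is named. The lowest p among the genes that fell, and among those that rose, belonged to the 2 genes that follow, which were chosen after their values were seen. ENSMUSG00000042406.7 had 304 ± 99.8 counts in the 5' UTR per 100 CDS counts in resting and 81.1 ± 21.4 in activated cells (SD, n = 3). The fitted log2 change was -2.17 (SE 0.31, edgeR adjusted p = 2.26e-04), and -1.83 with 1 scaling for both regions (edgeR adjusted p = 0.0367). Its CDS footprints rose (log2 change 3.00, SE 0.24, edgeR adjusted p = 6.04e-08), from 112 to 1116 counts over the 3 libraries of a group, while its 5' UTR counts went from 309 to 864. ENSMUSG00000024789.11 had 11.2 ± 4.67 counts per 100 CDS counts in resting and 93.3 ± 79.4 in activated cells (SD, n = 3). The fitted log2 change was 2.38 (SE 0.40, edgeR adjusted p = 0.00267), and 2.71 with 1 scaling for both regions (edgeR adjusted p = 0.0367). The ratio was 185, 50.7 and 44.3 in activated replicates 2, 3 and 4, and without activated replicate 2 the log2 change was 1.87 (edgeR adjusted p = 0.00134). Its log2 change in the CDS was 0.05 (SE 0.16, edgeR adjusted p = 0.802).

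The count of 21 genes varied with the libraries used: it was 5, 1 and 2 without resting replicate 2, 3 or 4, and 21, 5 and 36 without activated replicate 2, 3 or 4. Without resting replicate 3, the log2 change was -2.04 for ENSMUSG00000042406.7 (edgeR adjusted p = 0.0550) and 2.37 for ENSMUSG00000024789.11 (edgeR adjusted p = 0.111), close in size to those with all libraries. With 1 scaling for both regions 3 genes changed, these 2 among them. With a block for the replicate number 7 genes changed (1 higher, 6 lower).

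**Figure D3:**
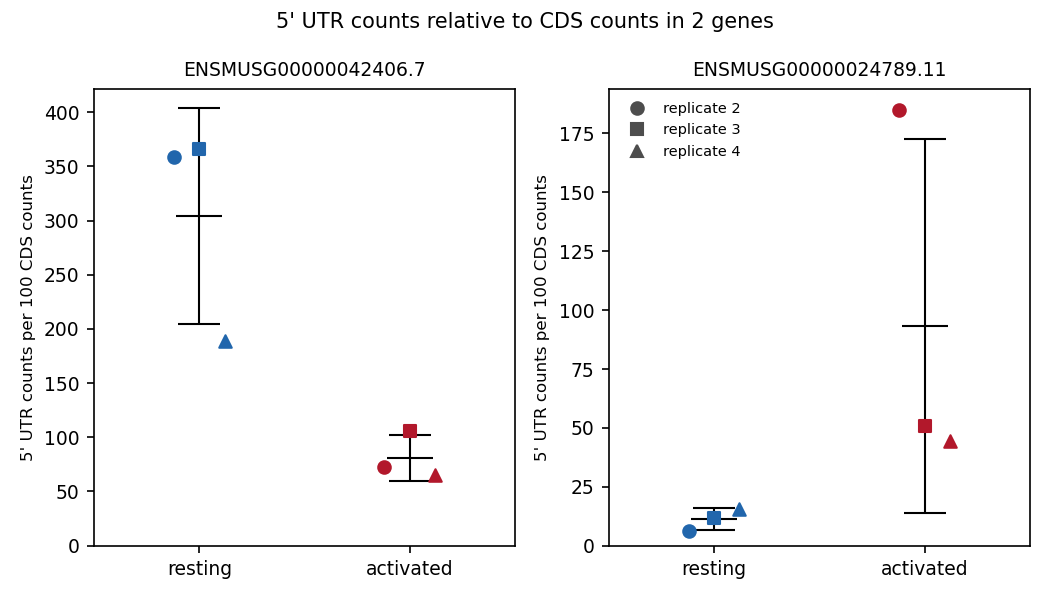
Counts in the 5' UTR per 100 CDS counts (vertical axis) in resting (blue) and activated (red) libraries for 2 genes chosen after their values were seen. Points are libraries, with their shape giving the replicate number, and bars are the mean ± SD (n = 3); the ratio was 304 in resting and 81.1 in activated cells for the first gene, and 11.2 and 93.3 for the second.

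Introns held 6.68%, 16.3% and 11.4% of exon and intron counts in resting replicates 2, 3 and 4, and 5.24%, 5.22% and 7.62% in activated replicates 2, 3 and 4 (exact permutation p = 0.2). A single gene, ENSMUSG00000029635.14, held between 15.9% and 76.6% of the intronic counts of a library, with 38 CDS counts over all 6 libraries; it was chosen after its values were seen. Its log2 change in introns was -1.19 (SE 0.85, edgeR adjusted p = 0.357), and it ranged from -0.64 without resting replicate 3 to -2.30 without activated replicate 4, never past the threshold with a library left out. Without it, introns held 4.31 ± 0.26% in resting and 3.60 ± 0.74% in activated cells (SD, n = 3; exact permutation p = 0.3).

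The 3' UTR held 3.23%, 1.89% and 1.54% in resting replicates 2, 3 and 4, and 3.08%, 1.72% and 1.03% in activated replicates 2, 3 and 4 (exact permutation p = 0.7). These shares differed more between replicates of a group than between the groups. In both groups they were highest in replicate 2 and lowest in replicate 4, and at each number the activated library was below the resting library. The permutation test takes no account of the number. ENSMUSG00000028420.12, also chosen after its values were seen, held between 31.8% and 46.4% of the 3' UTR counts of a library and had 49 CDS counts over all 6 libraries. Its log2 change in the 3' UTR was -0.28 (SE 0.32, edgeR adjusted p = 0.570), and it ranged from -0.02 without resting replicate 3 to -0.54 without resting replicate 4, never past the threshold with a library left out.

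**Figure D4:**
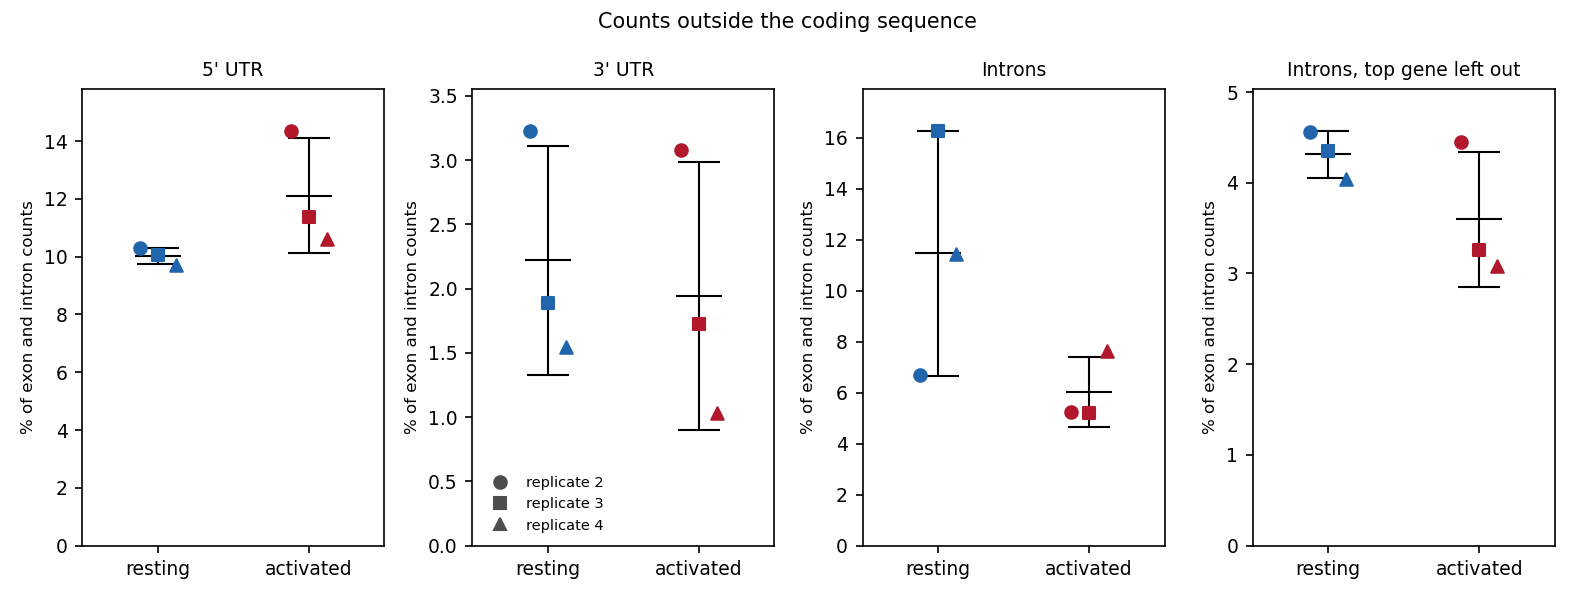
Share of exon and intron counts (percent) in the 5' UTR, the 3' UTR, introns, and introns without the gene that holds most intronic counts, in resting (blue) and activated (red) libraries. Points are libraries, with their shape giving the replicate number, and bars are the mean ± SD (n = 3); introns range from 5.22% to 16.3%, and from 3.08% to 4.56% without that gene.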

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

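Alternatives for the counting column, thinning, the 50 most abundant genes, the 5' UTR, the 3' UTR and introns were chosen after seeing the data. The number of genes changed in the CDS stayed within 1.5 times 3097 under all 21 alternatives (2192 to 3674), and no gene called there was called in the opposite direction under the 20 alternatives for which genes were matched. Lower genes numbered 2572 with library totals alone, 827 with DESeq2 and 918 at an adjusted p under 0.01, against 1464. By at least 2-fold, library totals alone gave 1390 lower genes against 734, and glmTreat against a 2-fold null gave 721 genes, 544 higher and 177 lower, asking for more than 2-fold. Leaving out each library gave 2654 to 3055 genes (1724 to 1837 by at least 2-fold), and the 4 named genes kept their direction and an adjusted p under 0.05 in edgeR, DESeq2 and limma fits, except that ENSMUSG00000024912.5 was not tested after thinning. The difference in the share of the 10 most abundant genes was 2.97 percentage points, 2.14 in exon counts, and 2.86 to 3.13 without each library.

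In 5' UTR counts, DESeq2 called 586 genes, 223 of them lower, against 924 and 436; leaving out each library gave 720 to 977. For 5' UTR relative to CDS counts, 1 scaling for both regions gave 3 genes (2 higher, 1 lower) against 21 (8 and 13), and leaving out each library gave 1 to 36 genes (0 to 12 higher, 1 to 24 lower). The older quasi-likelihood fit, used first for this result, gave 20; the newer one was chosen to match the CDS fit. The median log2 shift of the 5' UTR over the CDS with 1 scaling was 0.32, and 0.20 to 0.44 without each library. The difference in the 3' UTR share was -0.28 percentage points, and -0.84 to 0.23 without each library, changing sign without resting replicate 2 or activated replicate 4. In both groups this share was highest in replicate 2 and lowest in replicate 4, so leaving out such a library from a single group moves that group's mean alone. At each number the activated library was below the resting library. The cause of that order by number, and of the changes in counts above, was not tested. The 5' UTR difference was 0.951 to 2.83 and the intronic difference -7.84 to -3.03.

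Whether replicate numbers pair the libraries is not settled, and the main fit took no account of them. The deviations of same-numbered libraries from their group means correlated at 0.13, 0.07 and 0.23 for replicates 2, 3 and 4 across genes. Libraries with different numbers correlated at -0.16 to 0.01. All 6 libraries correlated best with their own number, a weak hint from the data and not the design. Deviations from a group mean cancel out over its 3 libraries, so positive values for same numbers push the others below them. The 6 matches are therefore not independent, and they do not test pairing. With the replicate number as a block, 3455 genes changed in the CDS; for 5' UTR relative to CDS counts the block gave 7 genes (1 higher, 6 lower). Not run, for want of gene names, were the alternatives for gene lists (camera with an estimated correlation, fry, and all scalings of list shifts), shares without mitochondrially encoded genes, and scaling without mitochondrial and ribosomal protein genes. The alternatives for normalized values did not apply to counts. Thinned to the smallest total, the libraries gave 2752 genes changed in the CDS.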

Other observations

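The tests on the 5' UTR, on introns, on abundant genes and on thinned libraries were chosen after the data had been seen, and the splits of the libraries before. Of the 3433 genes with enough counts in both regions, 250 had more 5' UTR than CDS counts in resting cells, summed over 3 libraries. In activated cells this held for 331 genes. The summed counts of activated cells include activated replicate 2, whose median gene had 35.6 5' UTR counts per 100 CDS counts, against 22.2 to 27.9 in the other libraries. The groups shared 202 of these genes, and 100 genes had more 5' UTR than CDS counts in all 6 libraries. Independent lists would share 24.1, but the same regions of the same genes were counted in both groups, so this comparison is no test. Counts were not divided by the length of either region. They carry no reading frame or fragment length, so 5' UTR counts are not shown to come from ribosomes. ENSMUSG00000042406.7, with 309 counts in the 5' UTR and 112 in the CDS in resting cells, had more in the CDS in activated cells by summed counts, though not in activated replicate 3 (105 per 100 CDS counts).

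The first pattern is the large number of genes whose CDS footprints changed. Activated libraries were on average deeper, and a difference in depth would predict far fewer genes once all libraries are thinned to 437200 counts; 2752 genes were then called, 88.9% of the number in the full libraries and 2609 of them among the 3097 called there, which argues against depth as the main cause. If a few genes took most counts, all others would fall together. The 50 most abundant genes went from 11.5% to 16.5% of CDS counts, which shifts all others by -0.084 on the log2 scale (standard error 0.0040). That was 22% of the median change of all other genes tested with library totals alone (-0.38). There 1075 other genes were higher. A common fall can only lower a gene, so it cannot be the source of their rise, and they test nothing further. For lower genes the shift decides nothing, since the 3097 calls used TMM scaling, which already takes out a common shift. The value of 22% also holds for the cutoff of 50 alone. The 999 genes at least 2-fold higher, chosen on these same libraries, went from 14.5% to 38.6% of CDS counts. A larger set of genes can therefore shift the others by more. With 10 splits of 6 libraries into 3 and 3, no share under 0.05 can be reached: the real split gave 3097 genes (1733 by at least 2-fold) and the highest of the other splits 0 in both counts, with 1 of 10 splits as large. Every other split puts resting and activated libraries together on both sides, which widens the spread within a side. Their 0s therefore do not show what chance gives between like libraries. The activation named by the labels stays open as a hypothesis, together with a change in mRNA level, which footprints alone do not separate from a change in translation.

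The second pattern is the higher mean intronic share in resting libraries. The groups overlapped, at 6.68% in resting replicate 2 and 7.62% in activated replicate 4 (exact permutation p = 0.2). Without ENSMUSG00000029635.14, 13.2% of the difference between the group means was left, consistent with a difference carried by a single gene. Whether that gene differs between resting and activated cells cannot be told apart from the spread between libraries, with an adjusted p of 0.357 in edgeR's fit of intronic counts. It had 38 CDS counts over all libraries, so its intronic counts may come from another RNA encoded in its introns, a hypothesis that was not tested, as no annotation was used. The library with the highest share of it was resting replicate 3, at 76.6% of intronic counts, and the lowest activated replicate 2, at 15.9%.

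The third pattern is the higher 5' UTR share in activated libraries, which holds in all 3 libraries over exon and intron counts and not over exon counts alone. Exon and intron counts include ENSMUSG00000029635.14, which held 76.6% and 67.4% of intronic counts in resting replicates 3 and 4 and so lowered their 5' UTR share. The separation of the groups therefore depends on the base. With 1 scaling for both regions, the median gene shifted by 0.32 (log2) toward the 5' UTR. Without activated replicate 2, 61.6% of the shift was left, and 55.6%, 77.6% and 46.6% when resting replicate 2, 3 or 4 was left out as well, so a shift from that library alone cannot be told apart from a shift in all activated libraries. Values per library go both ways: summed over these genes, 5' UTR counts per 100 CDS counts were 20.2, 21.7 and 19.7 in resting and 27.8, 20.8 and 19.5 in activated replicates 2, 3 and 4, so that activated replicate 2 alone stood apart, while the median gene had 22.5, 26.1 and 22.2 against 35.6, 27.9 and 25.0. For the genes that changed relative to the CDS, splits can give no share under 0.05. The real split gave 21 genes and the highest of the others 0, with 1 of 10 as large. For 5' UTR counts alone these were 924 and 0, again with 1 of 10. The other splits mix the groups here too, so their 0s are no measure of chance between like libraries.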
